A study of Mus musculus with 20 samples.

How the data were processed

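Nuclei of neurons and non-neurons were sorted from mouse hypothalamus at P0 and P21, and DNA methylation was measured by methylation-specific amplification followed by sequencing, with 5 libraries per group and 20 in all. Per the labels, each library came from a pool of 2 hypothalami of male mice. The deposited table holds raw read counts per SmaI/XmaI interval; that they are counts was taken from the values, which are whole numbers with a different total in each library. The submitters' processing notes name FastQC 0.10.1, cutadapt, Bowtie 0.12.9 and the mm9 genome build. How reads were counted per interval, and how reads mapping to several places were treated, is not given in the sources used here. Columns were assigned to libraries by age, cell type letter (N for neurons and G, read as glia from the series title, for non-neurons) and replicate number, and 0 columns belonged to other samples. Interval coordinates are those of the deposited table. A gene annotation of the mm9 build was not used here, and the one given is of another build (GRCm38), so intervals were not assigned to genes and the 15 gene lists fixed in advance, the genes to be named in any case and the tests by promoter and gene body were not run. They are not analysed here.

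The count of an interval depends on methylation of both flanking sites, on its length, on PCR and on depth, and reads carry no molecular identifiers. Totals ran from 5663740 to 9998110 reads per library, and 6237 of the 50782 intervals had no read in any library. Intervals were kept with filterByExpr of edgeR 4.0.16 (minimum count 10, total at least 15, which came to a CPM above 1.42 in at least 5 libraries), leaving 26679. Library sizes were scaled by TMM, one mean per group was fitted to all 20 libraries with the quasi-likelihood model (glmQLFit, robust), and each contrast was tested with glmQLFTest in R 4.3.3. The 5 comparisons were neurons against non-neurons at P0 and at P21, P21 against P0 in neurons and in non-neurons, and the interaction. Intervals with a Benjamini-Hochberg adjusted p under 0.05 over all tested intervals were called. The standard error of a log2 fold change is its size divided by the square root of the quasi-likelihood F. The biological coefficient of variation was 13.8%. CPM values use TMM-scaled library sizes, and principal components were taken on log2 CPM with a prior count of 2.

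Before the data were examined, a rule fixed which intervals are named: among called intervals with all 5 values of one group above all 5 of the other (not applied to the interaction) and a mean log2 CPM above the median of tested intervals, the 5 with the largest log2 fold change in each direction. This gave 50 named results over 36 distinct intervals. Under chance alone 2 groups of 5 are fully separated in 0.794% of arrangements, in either direction. Library-level measures were compared with two-sided exact permutation tests, and shares of calls per chromosome with Fisher's exact test. Overlaps of calls were set against independent lists (the product of the 2 list sizes over the number tested, per direction), simulated groups with no change (for correlations and covariances), and fits in which replicates 1 and 2 of a shared group went to one comparison and replicates 3 to 5 to the other.

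The functions that fit the model were tested on simulated counts drawn for the 26679 intervals with their means, dispersions and library sizes, with 200 intervals changed per comparison. At 4-fold, 100% of changed intervals were recovered for cell type at P0, 95.5% for cell type at P21, 97.0% for age in neurons, 93.9% for age in non-neurons and 78.8% for the interaction. At 2-fold, the shares were 68.7%, 68.7%, 59.7%, 68.7% and 44.8%, and at 1.5-fold 35.8%, 43.3%, 43.3%, 31.3% and 7.46%. Unchanged intervals called numbered 6, 6, 6, 18 and 1. Fewer intervals changed in these simulations than were called in the data. That makes the adjusted p stricter, so the shares recovered may be too low for these data.

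Alternatives fixed in advance were RLE, total-count and upper-quartile scaling, no filter and a filter of at least 20 reads in at least 5 libraries, DESeq2 1.42.0, limma-voom (limma 3.58.1), fits with only the compared groups, a 2-fold minimum, an adjusted p of 0.01 for overlaps, a replicate block and leaving out each library. Corrections for interval length (a lowess trend of each library, span 0.2) and for mean level (cyclic loess), thinning to the smallest library and fits of P0 subsets were added after the data were seen. Alternatives planned for normalized values (pseudocounts, a value filter) did not apply to counts. Plots were drawn with matplotlib 3.10.9.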

Results

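Cytosine methylation was profiled in the hypothalamus of male C57 mice, an inbred laboratory strain, on the day of birth (postnatal day 0, P0) and at postnatal day 21 (P21). At each age nuclei were sorted by fluorescence into neurons, which carry the nuclear protein NeuN, and non-neurons, which do not. Each of the 4 groups held 5 libraries, described as independent samples, and each sample pooled 2 hypothalami. The labels do not say whether neurons and non-neurons of one replicate number came from the same pool. The main fit did not pair them. The assay, methylation-specific amplification, first cuts unmethylated CCCGGG sites with SmaI and then methylated ones with XmaI. Adaptors are ligated to the XmaI ends, so that an interval is amplified when the sites at both of its ends are methylated. A higher normalised read count (CPM, relative to the TMM-scaled library size) therefore stands for more methylation at the 2 flanking sites, on a relative scale and not as a percent of molecules. The table listed 50782 intervals of 60 to 3000 bp on the mm9 assembly, by coordinates and without gene names, so intervals are given here by position and no gene, exon or promoter is assigned to them. Between 5663740 and 9998110 reads were counted per library. P21 neurons had the deepest libraries (mean 8998000 ± 906500 reads, SD, n = 5), above P21 non-neurons (6931000 ± 813700, SD, n = 5; two-sided exact permutation p = 0.0159, adjusted p = 0.0317 over 20 library-level tests). A total of 26679 intervals held enough reads to be tested, and these carried 99.57% of all reads.

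Libraries separated by age and by cell type. The first principal component of log2 CPM, with 44.6% of the variance, parted P0 from P21 libraries, and the second, with 20% of the variance, parted neurons from non-neurons at each age. The distance between neurons and non-neurons on the second component was larger at P21 than at P0. P0 neurons scored 31.1 to 33.7 and P0 non-neurons -13.8 to -4.11, whereas P21 neurons scored 42.2 to 46.2 and P21 non-neurons -73.5 to -60.9. Replicates of one group correlated at r = 0.964 to 0.983 across intervals. Set against counting error alone, which leaves out differences between samples and between amplifications, the chi-square per degree of freedom was 2.02 to 9.38 over 40 pairs. The third component (5.06%) parted P0 replicates 1 to 3 from 4 and 5 in both cell types, at 30.2 to 44.2 against -18.9 and -15.7 in neurons and at -16.2 to 9.22 against -27.2 and -42.6 in non-neurons.

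**Figure D1:**
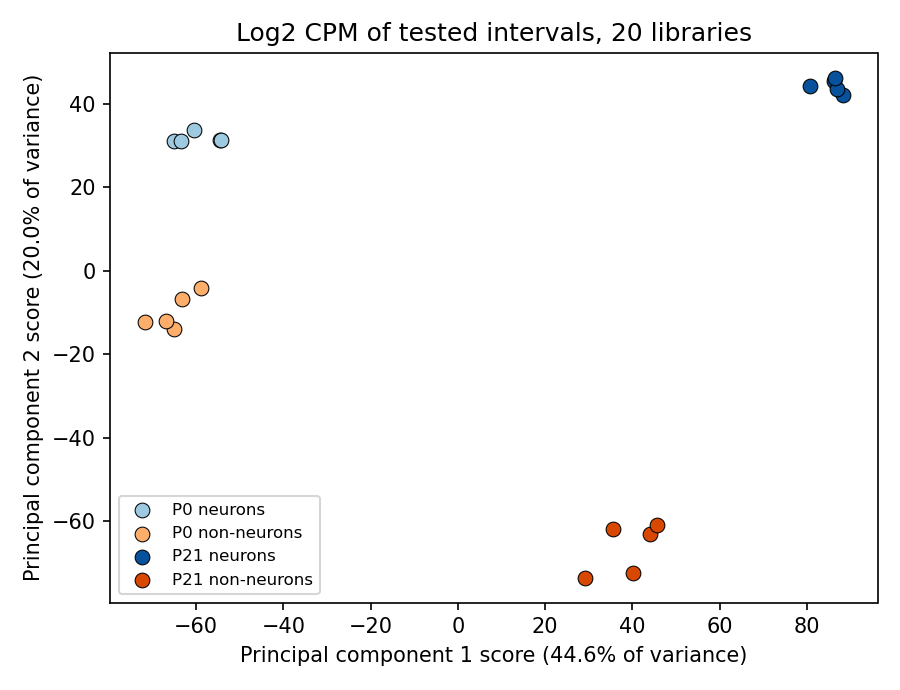
Scores of the 20 libraries on the first 2 principal components of log2 CPM; each point is a library and colours mark the 4 groups. P0 libraries lie at negative scores on the first component (44.6% of variance) and P21 libraries at positive scores, and neurons lie above non-neurons of their own age on the second (20%).

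Neurons and non-neurons were first compared at birth. Of the tested intervals, 2610 (9.78%) differed at P0, 1847 with more reads in neurons and 763 with fewer. The interval chr7:26031602-26032252 had 45.6 ± 7.81 CPM in P0 neurons against 3.24 ± 1.09 in P0 non-neurons (SD, n = 5 each), a log2 fold change of 3.81 ± 0.18 (SE; edgeR adjusted p = 2.5e-20), and held 42.7 ± 3.72 against 1.64 ± 0.63 CPM at P21. Also higher in neurons was chr8:93393071-93393598, at 35.6 ± 2.68 against 2.83 ± 1.44 CPM, and chr11:97302663-97302946, at 34.8 ± 2.84 against 3.89 ± 1.26 CPM. At lower read counts, chr7:86642731-86643606 (5.08 ± 1.74 against 0.24 ± 0.11 CPM) and chr12:119768027-119768594 (7.41 ± 2.09 against 0.76 ± 0.37 CPM) were higher in P0 neurons, and both reached more reads in neurons by P21 (37.4 ± 2.21 and 54.2 ± 6.91 CPM). In the other direction, chr14:65213241-65214128 had 1.93 ± 0.95 CPM in P0 neurons and 16.7 ± 2.53 in P0 non-neurons (log2 fold change -3.09 ± 0.25, SE; edgeR adjusted p = 7.3e-13). The interval chr8:123073824-123074613 had 1.43 ± 0.83 CPM in P0 neurons and 14.6 ± 1.82 in P0 non-neurons, and chr1:122500617-122501057 had 1.37 ± 0.53 and 11.3 ± 2.86. At least 2-fold differences were found at 449 intervals higher and 292 lower in neurons. The split into higher and lower calls depended on scaling: 70.8% of the calls were higher in neurons with TMM factors, 58.5% with library totals alone, 51.1% with upper-quartile factors and 56.2% with the length trend of each library removed. At 2-fold, 60.6% were higher with TMM and 48.6% with upper-quartile factors.

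At P21 the same contrast gave 9559 intervals (35.8% of those tested), 5552 higher and 4007 lower in neurons. Differences of 2-fold or more lay mostly on the neuronal side, with 2665 intervals higher and 884 lower. The interval chr9:96337839-96338589 had 65.2 ± 9.57 CPM in P21 neurons and 1.97 ± 1.08 in P21 non-neurons (SD, n = 5 each), a 32.2-fold difference (log2 fold change 5.01 ± 0.20, SE; edgeR adjusted p = 4.71e-23). Differences above 30-fold were also measured at chr5:28786478-28787412 (37.6 ± 4.38 against 0.98 ± 0.75 CPM), chr15:101833492-101834550 (42.5 ± 3.37 against 1.11 ± 0.38 CPM), chr8:93393598-93394580 (39.6 ± 3.70 against 1.05 ± 0.25 CPM) and chr12:110676177-110677092 (35.7 ± 4.22 against 1.05 ± 0.40 CPM). The interval on chromosome 8 shares a cut site with chr8:93393071-93393598, which was higher in neurons at P0. Among intervals with fewer reads in P21 neurons, chr1:94745671-94746930 had 3.46 ± 0.74 CPM in neurons and 47.3 ± 6.23 in non-neurons (log2 fold change -3.78 ± 0.14, SE; edgeR adjusted p = 3.38e-24). Lower in neurons as well were chr11:80296307-80297734, at 2.19 ± 0.43 against 35.6 ± 7.85 CPM, chr8:87230622-87231875, at 3.50 ± 0.91 against 49.9 ± 10.8 CPM, and chr14:65213241-65214128, at 1.03 ± 0.52 against 18.0 ± 2.94 CPM. With TMM factors 58.1% of the calls were higher in neurons, with library totals alone 45.8% and with upper-quartile factors 32.5%. Upper-quartile factors shifted the median log2 fold change of all intervals by -0.19, and 2-fold calls then still lay more often on the neuronal side (2119 higher, 1503 lower; 58.5% higher against 75.1% with TMM).

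Intervals that differed at birth mostly differed at P21 in the same direction when they were higher in neurons. Of the 1847 intervals higher in neurons at P0, 1587 (85.9%) were also higher at P21 and 12 were lower. Of the 763 lower in neurons at P0, 379 (49.7%) were lower at P21 and 135 were higher. Under the other scalings and the length correction 84.1% to 87.4% of the neuron-higher and 50.9% to 65.7% of the neuron-lower intervals kept their direction, and the neuron-lower intervals called at both ages numbered up to 887, with the length correction. The 1966 intervals called in the same direction at both ages compare with 499 for independent lists. These comparisons share no library. Independent lists take every tested interval as equally likely to be called. From the 6670 tested intervals with the fewest reads to the 6670 with the most, calls rose from 3.19% to 16.8% at P0. At P21 they rose from 22.9% to 47.4%. The numbers for independent lists, here and below, can therefore be too low. Across the 26679 intervals, which are not independent of each other, the log2 fold changes at P0 and P21 correlated at r = 0.458.

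**Figure D2:**
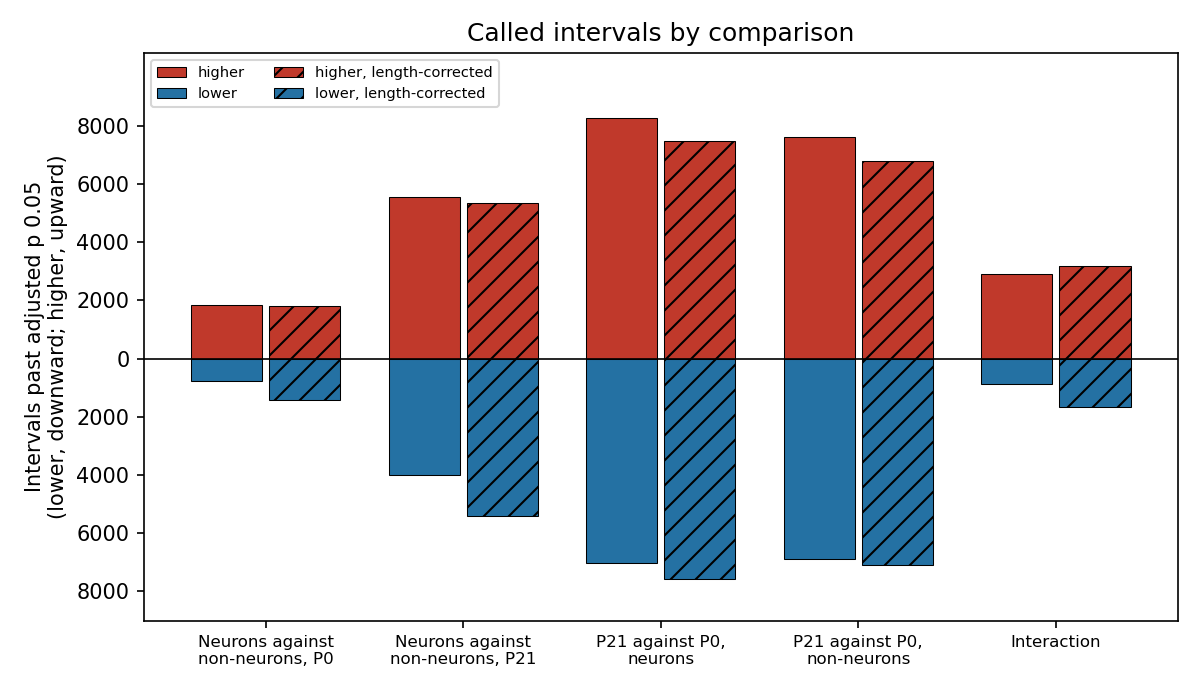
Number of intervals past an adjusted p of 0.05 in each comparison, upward for higher and downward for lower; plain bars are the counts with TMM factors and hatched bars those with the length trend of each library removed. Differences between cell types rose from 2610 at P0 to 9559 at P21 (3236 and 10760 after the length correction). Between P0 and P21 libraries, 15280 intervals differed in neurons and 14479 in non-neurons.

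Between P0 and P21, 15280 intervals (57.3%) changed in neurons, 8261 rising and 7019 falling, and 3821 rose and 2145 fell by 2-fold or more. Several intervals with almost no reads in P0 neurons became strongly covered. The interval chr3:84469581-84470384 rose from 2.21 ± 0.77 to 189.7 ± 17.2 CPM (SD, n = 5 each), an 85.8-fold increase (log2 fold change 6.42 ± 0.18, SE; edgeR adjusted p = 3.84e-27), while non-neurons rose from 1.24 ± 0.39 to 8.86 ± 3.10 CPM. The interval chr19:7000511-7001501 rose from 1.20 ± 0.46 to 84.3 ± 5.55 CPM in neurons, chr9:96337839-96338589 from 0.97 ± 0.35 to 65.2 ± 9.57, chr1:133868034-133868955 from 0.74 ± 0.45 to 46.9 ± 3.38 and chr15:101833492-101834550 from 0.49 ± 0.27 to 42.5 ± 3.37. Reads were lost at chr8:12671941-12673001, which fell from 13.7 ± 1.60 to 0.58 ± 0.17 CPM in neurons (log2 fold change -4.54 ± 0.22, SE; edgeR adjusted p = 9.58e-21). They were also lost at chr10:80720373-80720997 (21.8 ± 4.33 to 1.28 ± 0.75 CPM), chr1:94745671-94746930 (45.8 ± 5.59 to 3.46 ± 0.74), chr15:98001052-98001467 (25.7 ± 0.53 to 2.98 ± 0.78) and chr8:107994743-107995280 (26.4 ± 3.12 to 3.15 ± 1.29).

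In non-neurons 14479 intervals (54.3%) changed with age, 7600 rising and 6879 falling, and 2860 rose and 2083 fell by 2-fold or more. The interval chr9:32351428-32352485 rose from 1.48 ± 0.59 to 29.3 ± 5.68 CPM (SD, n = 5 each; log2 fold change 4.28 ± 0.24, SE; edgeR adjusted p = 4.5e-18) and chr8:87230622-87231875 from 4.26 ± 1.04 to 49.9 ± 10.8 CPM. Rises were also measured at chr13:53330353-53331276 (2.04 ± 0.81 to 21.6 ± 4.49 CPM), chr9:20839609-20840797 (1.06 ± 0.54 to 10.4 ± 2.34) and chr2:115845505-115846922 (1.94 ± 1.08 to 17.8 ± 2.96). All of these named rises were shared by neurons. There chr9:32351428-32352485 went from 1.35 ± 0.98 to 14.2 ± 1.95 CPM and chr8:87230622-87231875 from 0.55 ± 0.34 to 3.50 ± 0.91. The interval chr8:113885105-113885740 fell from 55.3 ± 4.94 to 8.23 ± 1.09 CPM in non-neurons (log2 fold change -2.75 ± 0.11, SE; edgeR adjusted p = 1.38e-22), against 80.7 ± 5.63 and 63.7 ± 2.50 CPM in neurons. In chr6:146449480-146450213 non-neurons fell from 20.3 ± 2.97 to 2.39 ± 0.97 CPM whereas neurons rose from 27.4 ± 4.16 to 36.8 ± 4.01. Larger counts fell in both cell types at chr2:166455562-166456511 (195.2 ± 23.9 to 29.1 ± 4.88 CPM in non-neurons) and chr13:51622074-51622806 (95.6 ± 11.1 to 15.6 ± 2.42).

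The 2 cell types shared most of their change with age. In both, 5391 intervals rose and 4917 fell, together 10308 against 4163 for independent lists, and 546 changed in opposite directions. Across intervals the age changes of the 2 cell types correlated at r = 0.699, and the comparisons share no library. Any difference in preparation between P0 and P21 libraries would still enter both comparisons alike. The labels do not separate preparation from age. The split into rising and falling intervals depended on scaling. With TMM factors 54.1% of the calls in neurons and 52.5% in non-neurons rose, and with library totals alone, which shifted the median of all intervals by 0.20 in neurons and 0.22 in non-neurons, 69.1% and 70.6% rose. At 2-fold 64% and 57.9% rose with TMM, 77.9% and 77.7% with totals alone, and 47.0% rose in non-neurons after the length correction. The median change with age also followed interval length. It was lowest, at -0.32 on the log2 scale in neurons and -0.34 in non-neurons, among intervals of 400 to 800 bp. It was highest, at 0.53 and 0.43, among those of 1600 to 2000 bp. The course was not a steady rise: the medians were 0.08 and 0.40 at 100 to 200 bp, and -0.08 and -0.14 at 2500 to 3000 bp. After removal of the length trend of each library, 15054 intervals were called in neurons and 13878 in non-neurons, and 12337 and 10978 of them were called in the same direction without it, whereas 9 and 8 were called in the opposite direction. With the length and mean level corrections together, 339 calls in neurons and 418 in non-neurons turned direction.

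**Figure D3:**
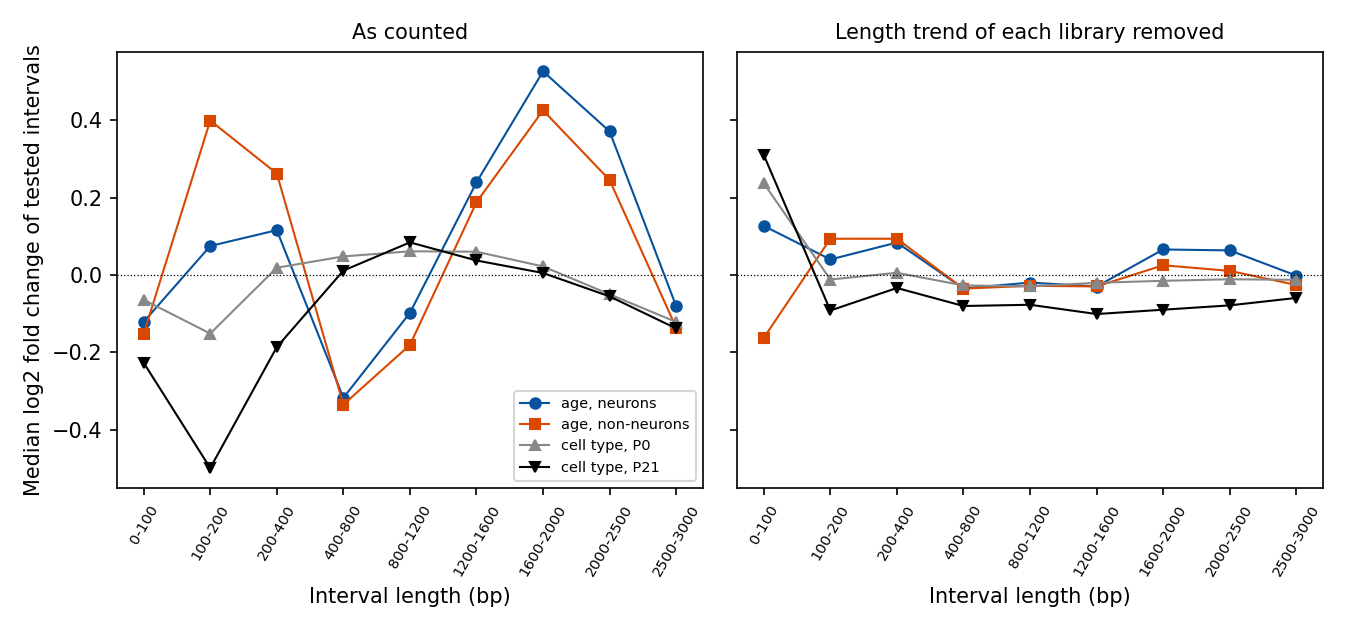
Median log2 fold change of the tested intervals in bins of interval length (bp), for age in each cell type and for cell type at each age, as counted (left) and with the length trend of each library removed (right). As counted, the age changes were lowest at 400 to 800 bp (-0.32 and -0.34) and highest at 1600 to 2000 bp (0.53 and 0.43), without a steady rise. They stayed between -0.04 and 0.07 in those bins after the correction.

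The interaction of cell type and age tested whether the neuron minus non-neuron difference changed between P0 and P21. It did at 3772 intervals: the difference rose at 2908 and fell at 864. By 2-fold or more it rose at 1652 and fell at 322. Of the 2908 intervals, 1010 rose in neurons with no call in non-neurons, 486 rose in neurons and fell in non-neurons, 466 rose in both, 575 fell in non-neurons with no call in neurons and 364 fell in both. Of the 864 intervals, 321 fell in neurons with no call in non-neurons, 268 fell in both, 171 rose in non-neurons with no call in neurons and 60 fell in neurons and rose in non-neurons. These numbers depended on the processing: with the length correction the difference fell at 1668 intervals, 599 of them falling in neurons with no call in non-neurons, and with upper-quartile factors it fell at 1943. The interval chr5:135729398-135730353 crossed over: it was lower in neurons at P0 (2.28 ± 0.89 against 9.10 ± 3.24 CPM, SD, n = 5 each) and higher at P21 (99.0 ± 6.39 against 8.88 ± 1.97), an interaction of 5.47 ± 0.28 on the log2 scale (SE; edgeR adjusted p = 7.86e-17). The interval chr1:133868034-133868955 crossed over in the same way, from 0.74 ± 0.45 against 5.05 ± 0.93 CPM to 46.9 ± 3.38 against 10.2 ± 1.01. Neurons lost reads with no call in non-neurons at chr10:126695823-126696812, where neurons went from 65.6 ± 5.38 to 12.7 ± 2.20 CPM and non-neurons from 84.2 ± 2.95 to 91.9 ± 12.7 (interaction -2.51 ± 0.15, SE; edgeR adjusted p = 1.87e-16). At chr15:83935341-83935992 neurons went from 50.9 ± 5.92 to 6.93 ± 1.21 CPM and non-neurons from 52.7 ± 6.59 to 32.9 ± 1.17. With TMM factors 77.1% of the interaction calls were positive, with upper-quartile factors 56.2%, with the length correction 65.5% and with the length and mean level corrections together 63.3%. At 2-fold this share stayed between 76.7% and 83.7% under the 5 scalings tried.

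**Figure D4:**
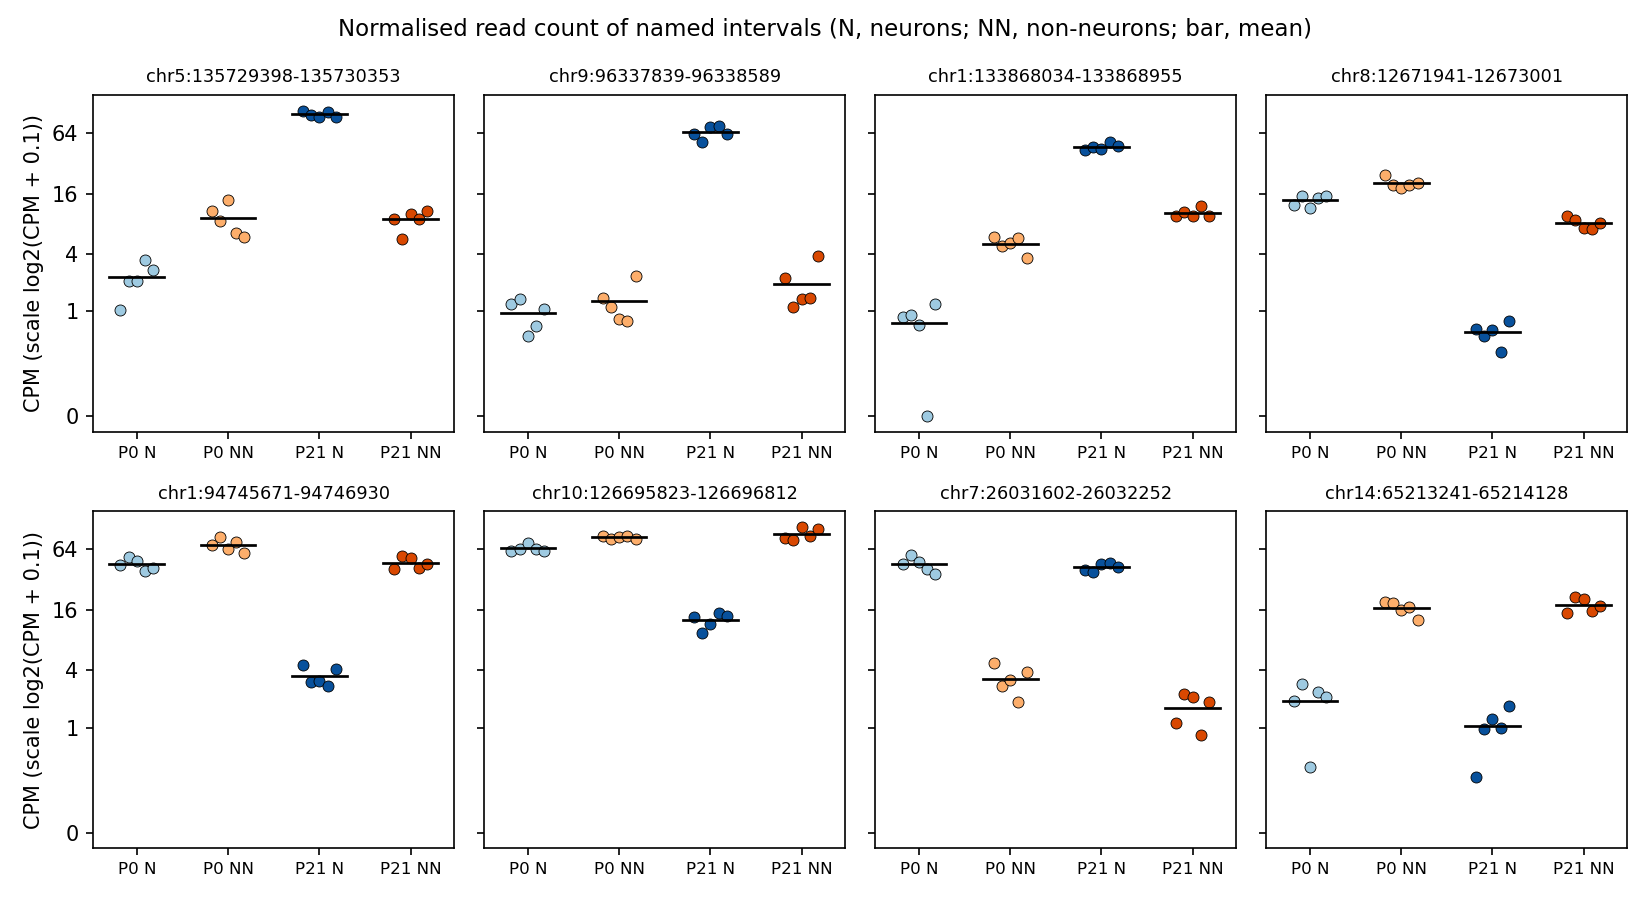
CPM of 8 named intervals in each library on a log2(CPM + 0.1) scale, grouped as P0 neurons (P0 N), P0 non-neurons (P0 NN), P21 neurons (P21 N) and P21 non-neurons (P21 NN); points are libraries and bars are group means (n = 5). The first 3 panels rose in neurons with age (to 99.0, 65.2 and 46.9 CPM), the next 3 fell in neurons (to 0.58, 3.46 and 12.7 CPM), and the last 2 differed between cell types at both ages.

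The P21 differences of 2-fold or more were also set against the age change in each cell type. Of the 2665 intervals higher in P21 neurons, 35.8% had risen in neurons with no call in non-neurons, 14.2% had risen in neurons and fallen in non-neurons, 15.8% had risen in both, 15.7% had fallen in non-neurons with no call in neurons, 11.5% had fallen in both and 6.68% had no age change called in either. Of the 884 lower in P21 neurons, 29.6% had fallen in neurons with no call in non-neurons, 23.1% had fallen in both, 16.7% had risen in non-neurons with no call in neurons and 22.1% had no age change called in either. Over all tested intervals, 8.94% rose in neurons with no call in non-neurons, and 1.82% rose in neurons and fell in non-neurons. In both cell types 20.2% rose and 18.4% fell. Another 5.53% fell in non-neurons with no call in neurons, and 7.65% fell in neurons with no call in non-neurons. A rise in non-neurons with no call in neurons was found at 8.055%. Over all calls, cell type at P21 and age in neurons had the same direction at 5015 intervals (2773 for independent lists) and opposite directions at 1375. Higher in P21 neurons and risen in neurons were 3008 intervals (1719 for independent lists), and lower and fallen were 2007 (1054). Cell type at P21 and age in non-neurons had opposite directions at 3519 intervals (2573 for independent lists) and the same direction at 2084. The excess lay mostly on one side: 2334 intervals were higher in P21 neurons and fell in non-neurons (1432 for independent lists), whereas 1185 were lower in P21 neurons and rose in non-neurons (1141). Both of these pairs of comparisons share the 5 libraries of one P21 group. With the shared libraries split between the 2 comparisons, 3863 intervals overlapped in neurons (1913 for independent lists of the split fits) and 2437 in non-neurons (1766, with 1888 against 1104 on the neuron-higher side and 549 against 662 on the neuron-lower side). Simulated groups with no change had 0 calls in these comparisons and so give no chance overlap. Across intervals the log2 fold changes correlated at r = 0.486 in neurons and -0.144 in non-neurons, and at 0.46 and -0.50 in the simulated groups, where the shared libraries alone set the value. The covariance was 0.387 in neurons (0.024 in simulated groups) and -0.0952 in non-neurons (-0.026 in simulated groups).

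Called intervals of one direction sometimes lay side by side. One of the longest runs for cell type at P21, with 6 intervals and chosen after its values were seen, lay at chr11:74978428-74981570. All 6 were higher in P21 neurons, by 2.56 to 3.56 on the log2 scale. The interval chr11:74978836-74979938 rose from 3.02 ± 0.73 to 48.2 ± 4.93 CPM in neurons (SD, n = 5 each) and was at 4.74 ± 1.22 and 5.20 ± 1.57 in non-neurons. The interval chr11:74980722-74981570 rose from 0.23 ± 0.18 to 24.9 ± 3.74 CPM in neurons and was at 0.80 ± 0.55 and 2.71 ± 0.74 in non-neurons. Neighbouring intervals of the run share cut sites, with the exception of 1 gap between 74979938 and 74980026, so their counts are not independent.

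**Figure D5:**
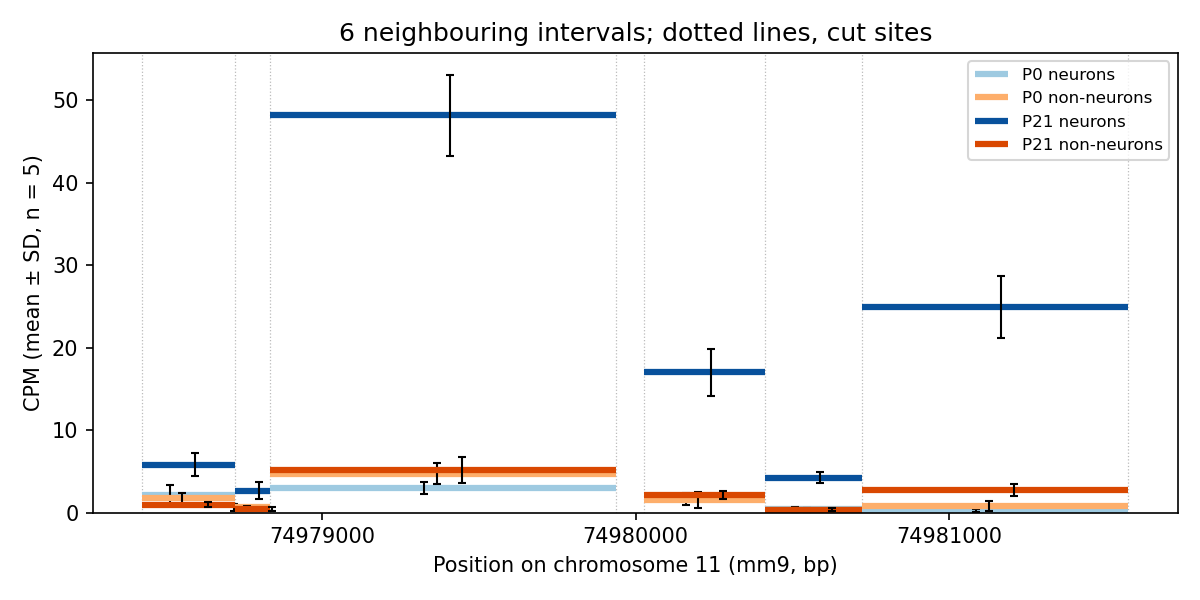
CPM (mean ± SD, n = 5) of 6 neighbouring tested intervals on chromosome 11 (mm9 position in bp) in the 4 groups; horizontal bars span each interval and dotted lines mark cut sites. P21 neurons lie above the other groups in each interval, reaching 48.2 CPM in the interval that starts at 74978836.

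Calls were spread unevenly over chromosomes, and the X chromosome stood apart. Of its 577 tested intervals, 9.7% were higher in neurons at P21 against 21.1% elsewhere (two-sided Fisher's exact test, adjusted p = 3.13e-11 over the 42 tests of the comparison), and 9.88% were lower against 15.1% (adjusted p = 0.00366). A positive interaction was called at 1.73% of X intervals against 11.1% elsewhere (adjusted p = 4.29e-16), and a negative one at 1.04% against 3.29% (adjusted p = 0.0161). With age in non-neurons, 12.5% of X intervals fell against 26.1% elsewhere (adjusted p = 1.39e-13), and 37.4% rose against 28.3% (adjusted p = 2.02e-05). After the length correction the latter shares were 29.5% and 25.3%, and those falling were 13.2% and 26.9%. The rise was not particular to X: on chromosome 3, 35.2% of intervals rose in non-neurons, and 32.6% after the length correction. The share of all reads on X intervals was 0.878% ± 0.026 in P0 non-neurons and 1.00% ± 0.057 in P21 non-neurons (SD, n = 5 each; two-sided exact permutation p = 0.00794, adjusted p = 0.0198), and it was 0.911% ± 0.027 and 0.940% ± 0.026 in neurons (exact permutation p = 0.135). Neighbouring intervals are not independent, so these tests describe the intervals listed and their p-values are too small as statements on the chromosome.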

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

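The tests of length bias in this part were chosen after the results were seen. The neuron minus non-neuron difference changed with age at many intervals by the interaction test: it rose from P0 to P21 at 2908 and fell at 864 (3172 and 1668 with the length correction). The named intervals with the largest rise were chr5:135729398-135730353 (5.47 on the log2 scale), chr9:96337839-96338589 (5.35), chr1:133868034-133868955 (4.93), chr19:7000511-7001501 (4.51) and chr15:101833492-101834550 (4.28). Those with the largest fall were chr8:12671941-12673001 (-3.21), chr1:94745671-94746930 (-3.15), chr10:126695823-126696812 (-2.51), chr11:80296307-80297734 (-2.39) and chr15:83935341-83935992 (-2.20).

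Cell types differed at 3.66 times as many intervals at P21 as at P0. Deeper P21 neuron libraries do not account for it, since the ratio was 3.67 with every library thinned to the smallest, and neither does length bias, since it was 3.33 with the length trends removed. If the 2 gates had been equally mixed at P0, shrinking the 2-fold P21 differences to their P0 size would take 36.4% mixing for neuron-higher and 33.4% for neuron-lower intervals, which would hold every P0 difference under 0.80 and 1.00 on the log2 scale. By 2 SE, 421 P0 intervals lay beyond these limits (306 neuron-higher, 115 neuron-lower). The limits take the P21 differences as already present at P0, as this explanation does, and both gates as equally mixed, which was not measured. The limits also rest on intervals chosen for a 2-fold difference at P21. This choice can make the mixing too large and the limits too low. The 421 intervals therefore do not decide whether mixing made the P0 differences smaller. Unequal mixing was not tested, and mixing at P0 stays open as all or part of the source. A difference between the 2 cell types that grows from P0 to P21 stays open as well.

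In 100 splits of the libraries, the real one was the only 1 to reach its count, for each of the 5 counts. For cell type and for age this argues against groups that do not differ at all. The other splits mix the real groups, so real differences add to their spread and lower their calls. They therefore do not show how many of the real calls arise by chance. The real split of the 10 P0 libraries gave 2760 intervals and the highest other split 100, and at P21 these were 9351 and 6. For age the counts were 14974 against 1 in neurons and 13531 against 0 in non-neurons. For the interaction, with cell type reassigned within each age, they were 3772 against 0. That reassignment also mixes the cell types, whose difference then adds to the spread, so it cannot test the interaction alone. The P0 split with 100 intervals placed P0 neuron replicates 1 to 3 together with P0 non-neuron replicates 2 and 3. With 1 exception (P0 non-neuron replicate 1) this parts P0 replicates 1 to 3 from 4 and 5, the division seen in both cell types on the third principal component, and points to a structure of the samples. With that division as a term in the fit, cell type at P0 gave 2762 intervals.

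Single libraries stood far from the other 4 of their group in 6 of 120 groups checked. The rule was a gap to the nearest library above 0.71 of the range of the group. For independent, normally distributed values it flags about 1 in 20. The groups checked share libraries and most are named intervals chosen from these data, so the equal rate does not show that the 6 arose by chance. P21 non-neuron replicate 1 had 35220 intervals with a read (others 34640 to 34800), and in P0 neuron replicate 2 the median read lay in an interval of 769 bp (others 758 to 761 bp). At chr8:93393071-93393598, P0 non-neuron replicate 1 had 5.35 CPM (others 1.77 to 2.57). At chr1:122500617-122501057, P0 non-neuron replicate 2 had 6.42 CPM (others 11.6 to 13.4). At chr3:84469581-84470384, P21 neuron replicate 2 had 160 CPM (others 192.4 to 202.1). At chr10:126695823-126696812, P0 neuron replicate 3 had 74.7 CPM (others 61.4 to 65.0).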

How the results depend on the processing

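All 50 named results kept their direction and stayed called under each alternative run (780 values) and without each library in turn (1000 values). The named intervals were chosen from these data as the largest changes, so this was likely from the start and does not extend to other calls. The 2-fold minimum and the adjusted p of 0.01 are among the alternatives and only set stricter cutoffs on the main fit. Leaving out 1 library gave 2240 to 2764 intervals for cell type at P0, 8697 to 9688 at P21, 14629 to 15667 for age in neurons, 13572 to 14713 in non-neurons and 3447 to 3923 for the interaction. Requiring a 2-fold change, a stricter rule by construction, left 741, 3549, 5966, 4943 and 1974 intervals, and overlaps of 499 (both ages), 2945 (age in both cell types), 1641 (P21 and age in neurons) and 682 (P21 and age in non-neurons, opposite directions). The last overlap was 2288 at an adjusted p of 0.01, against 3519. Within P0 replicates 4 and 5 alone, with fewer samples, cell type at P0 gave 978 intervals. Total counts under the other scalings, filters, tools and corrections stayed within 1.5 times the main count, whereas the split into higher and lower moved by over 10 percentage points under some, as given with each comparison; the cause was not tested. Counts of one direction moved more: lower in neurons went from 763 to 1699 at P0 (length and level corrected) and from 4007 to 8875 at P21 (upper-quartile), and negative interactions from 864 to 1943 (upper-quartile). With the mean level correction 140 age calls in neurons and 110 in non-neurons turned direction, and with length and level corrected together 339 and 418. The labels do not say whether replicate numbers pair the libraries, and the rule set for it was not met (3 of 5 pairs at P0 and 2 of 5 at P21 had correlations over 0.1, and at each age 4 of 10 libraries correlated best with their own number). With replicate number as a block, the counts were 3619, 11068, 15796, 15014 and 5128, and 67.0% of interaction calls were positive (77.1% without it). The gene lists with their 3 alternatives were not run. Weak changes are missed at this depth, spread and number of libraries: simulated 1.5-fold interactions were recovered at 7.46%, and thinning every library to the smallest gave 3482 interaction calls against 3772.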

Other observations

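The bound on library bias in the first length test was set after the length trend had been seen, and the X tests other than higher in neurons at P21 were chosen after the X shares had been seen. Runs of neighbouring intervals changed together in other places too, all chosen here after their values were seen. At chr7:51787803-51796844, 8 intervals fell with age in both cell types, and the highest of them, chr7:51795061-51795844, went from 813.7 ± 102.3 to 455.1 ± 30.4 CPM in neurons and from 904 ± 75.3 to 561 ± 63.2 in non-neurons (SD, n = 5 each). After the length correction 1 of the 8, chr7:51788467-51788957, was no longer called in non-neurons (log2 fold change -0.35 before and -0.08 after, edgeR adjusted p = 0.356). At chr7:106460291-106466404, 6 intervals were lower in P21 neurons. In the outermost, chr7:106460291-106460689, neurons had 0.75 ± 0.28 CPM at P0 and 0.70 ± 0.60 at P21, against 7.75 ± 0.38 and 7.44 ± 1.33 in non-neurons. Within the run, chr7:106465077-106465500, the next to last interval, had 246.4 ± 8.73 CPM in P0 neurons and 247.1 ± 21 in P0 non-neurons, and 157.1 ± 19.4 and 347.6 ± 32.3 at P21. At chr19:6501492-6505533, the neuron minus non-neuron difference fell at 5 intervals, by 1.02 to 1.99 on the log2 scale.

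Neighbouring intervals share methylation of a common cut site by construction, so intervals with a gap between them were examined. Of 383 neighbour pairs 1 to 1000 bp apart, 53 were called in the same direction for cell type at P21, against a median of 25 and a highest value of 39 in 200 shuffles of the calls among intervals of like level and length. Same-direction pairs also exceeded the highest shuffle at 1001 to 10000 bp (280 against 208) and at 10001 to 100000 bp (780 against 714). Over 100000 bp apart, 319 pairs lay below the shuffled median of 406. The shuffles did not match intervals on spacing, so this excess alone does not show that close neighbours change together. That cell type differences extend beyond single sites stays a hypothesis. The correlation of log2 fold changes between neighbours was 0.674 with a shared site, 0.494 at 1 to 1000 bp, 0.133 at 1001 to 10000 bp and 0.041 at 10001 to 100000 bp.

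The change with age followed interval length in both cell types. The swing across length bins in the 12589 intervals sharing no cut site was 1.40 times that in the 14090 that share one. These swings were 0.936 and 0.669 on the log2 scale, so the trend was not confined to intervals that share a site. Length is itself the distance between the flanking cut sites, so length bins still sort intervals by the spacing of sites. The comparison therefore cannot separate length from site density, and a property of regions dense in cut sites stays open. Libraries of one group also differed along length: the widest swing of a library against its own group, in P21 non-neuron replicate 1, was 0.681 times the mean swing with age, and the median library swing was 0.261 against 0.845 and 0.761 for age. Size or amplification bias that differs between libraries is thus a candidate explanation for part of the trend. Library preparation and age cannot be separated with these labels, so an age difference that itself follows length stays open as untested.

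X intervals were compared with 10000 random autosomal sets matched on mean level and length. In these, 16.98% to 23.05% (95% range) were higher in neurons at P21, and the lowest set had 13.7%, against 9.705% of X intervals. On the other side 12.8% to 18.4% were lower in P21 neurons, against 9.88% of X intervals. For a positive interaction the matched range was 8.49% to 13.3%, against 1.733% (permutation p = 2e-04, the smallest these sets can give; adjusted p = 3e-04 over 9 tests). With age 19.24% to 25.65% fell in neurons, against 16.12% of X intervals, and 18.0% to 24.1% in non-neurons, against 12.48%. Each of these 5 X shares lay below all matched sets, though narrowly for lower in P21 neurons (lowest set 10.23%) and falling in neurons (16.64%). Lower counts or other lengths are thus argued against, least firmly for these 2 shares. The sets drew autosomal intervals singly, whereas X intervals include neighbours that are not independent. The matched ranges are therefore too narrow and the p-values too small. For a negative interaction (1.04% of X intervals) and higher in neurons at P0 (3.64%) the lowest sets reached 0.693% and 2.43%, below the X shares, although the matched ranges were 1.91% to 4.68% and 3.99% to 7.63%, and counts or lengths stay open there. The shares that rose with age did not run low in this way: in non-neurons 37.44% of X intervals rose, above the matched 25.13% to 32.06% (permutation p = 2e-04), and in neurons 27.56%, inside 27.38% to 34.32% (p = 0.075). Other properties of the X chromosome in males were not tested.

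Mean level also went with the age change: in the 6670 intervals with the most reads the median log2 fold change was -0.21 in neurons and -0.20 in non-neurons, and in the next 6669 by mean level 0.21 and 0.18. Intervals that share a cut site fell with age more often than the others, with 30.0% against 22.2% in neurons and 29.7% against 21.4% in non-neurons, as raw shares. Stratified by level and length, the Mantel-Haenszel odds ratios were 1.5 (adjusted p = 3.8e-38 over 10 tests) and 1.56 (adjusted p = 1.22e-44). Intervals that share a site are not independent, so these p-values are too small.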
